A study of Mus musculus with 8 samples.

How the data were processed

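Droplet single-cell RNA sequencing was performed on cells from the brains of C57BL/6 mice carrying GL261, a mouse glioma line inoculated intracranially. Cells were isolated 20 days after inoculation. There were 8 groups with 1 library each, and each library pooled cells of 3 mice, so no group has a replicate library. Per the labels, 6 libraries held cells sorted as CD45.2-positive and viable, and 2 held all viable cells, with immune and tumour cells together. Libraries were made with the 10x Genomics 3' kit.

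The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger. Per the file headers, Cell Ranger 5.0.0 wrote the 2 diet libraries of the CD45.2 sort without antibody and Cell Ranger 6.1.2 wrote the other 6. Reads were aligned to mm10. The options used for counting, intronic reads included, are not given in the sources used here. Gene positions were taken from GENCODE vM21.

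Barcodes with under 200 genes or under 500 UMIs and those with over 10% mitochondrial UMIs were left out. Doublets were scored with Scrublet in each library, and the barcodes with the highest scores were removed at a share in proportion to the number of barcodes, because the automatic threshold marked 0 to 446 barcodes per library and failed in several. This share was chosen after the automatic threshold had been seen and removed 61 to 1115. In all, 2369 to 10029 cells were kept per library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and cells of all 8 libraries were clustered together with the Leiden algorithm (15 neighbours, resolution 1, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, Python 3.11.15), with no integration across libraries. Clusters were named from marker lists. Part of the naming rule was set after the clusters had been seen: at least 3 markers had to be detected in 25% of a cluster's cells, the score of the runner-up had to stay under a share of 0.85 of the best, T-cell subset markers were added to the T-cell set, and clusters with 8 or more T-cell markers could not be named innate lymphoid cells. Clusters failing these rules stayed unnamed.

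Within each class, UMIs were summed per library and expressed as CPM of the class sum. Folds are log2 ratios of CPM with 1 count added to each sum, for genes with at least 20 UMIs over the 2 sums and classes with at least 50 cells in both libraries. With 1 library per group there is no standard error and no test within a pair. Shares have exact Clopper-Pearson 95% intervals and sums have exact Poisson 95% intervals. The interval of a ratio of shares is made of quotients of the share bounds, lower over upper and upper over lower. It is not an exact 95% interval. A share of 0 is given instead with the limit that 3 counts of the total allow. These intervals and limits cover counting error only, not differences between mice, pools or preparations. A fold against a sum of 0 is given as a bound, with 3 counts in place of the 0 in that library's class sum. Shares of T cells with a UMI of a gene were taken after thinning every cell to 1500 UMIs, leaving out shallower cells, and the same share in microglia serves as the background from free RNA. In the CD8 gate a T cell has a UMI of Cd8a or Cd8b1 and none of Cd4, and in the CD4 gate the reverse.

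Gene lists were fixed before the data were examined, as were the other filters, the tests, the rule for named genes and most of the other settings compared. A list is described by the median log2 fold of its members (at least 5 measured) and by the percentile of that median among 10000 random lists of the same size, matched on expression in 20 bins. Medians at or below the 2.5th or at or above the 97.5th percentile are described as low or high for that pair of libraries. This is a description of 2 libraries and not a test. Named genes were, for each pair in T cells, microglia, monocytes or macrophages and the cluster with glioma markers, the 3 highest and 3 lowest folds among genes with at least 100 UMIs and 50 CPM in 1 library, outside mitochondrial, ribosomal, haemoglobin, immunoglobulin, variable receptor and unnamed gene models. To these were added up to 2 highest and 2 lowest members of each list outside the percentiles, and a fixed set of effector, checkpoint, macrophage, microglia and glucose-responsive genes. 1 result chosen by this rule is not reported here. Genes and clusters named outside this rule were chosen after their values were seen: Cd8b1, Trbc1, Tcrg-C1 and Trdc in T cells, the T-cell clusters with Foxp3 or Trdc, Retnlg and S100a8 in microglia, S100a9 in the few cells of a class, and the markers of unnamed clusters.

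The effect of the high-glucose diet over the 3 pairs of specific-pathogen-free (SPF) libraries was tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on class sums, with pair and diet as terms, TMM scaling, filterByExpr and the Benjamini-Hochberg procedure at 0.05. This leaves 2 residual degrees of freedom and treats the pairs, which differ in antibody and sort, as replicates of the diet effect. The test also borrows spread from other genes, with prior degrees of freedom of 8.9 in T cells, 18.13 in microglia and 9.26 in monocytes or macrophages. The SE given with a fold is the size of the fold over the square root of the F statistic. It is thus not the spread of the 3 pairs for that gene. No paired analysis by replicate number was possible because each group has 1 library. For this test the named genes were the 10 largest folds past the threshold with 1 sign in every pair and, where fewer than 5 passed, the 5 highest and 5 lowest of 1 sign and at least 1.5-fold in every pair. A pair with 0 UMIs of a gene in both libraries was at first given a sign by the added count and was set to have none after the values were seen. Class shares over the 3 pairs were compared with an exact two-sided sign-flip test, whose smallest possible p is 0.25. Correlations of folds between pairs are across genes with at least 100 UMIs, which are not independent replicates.

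The diet test was tested on simulated data with the real genes, depths and spread. Of 100 genes changed 2-fold it recovered 72 in T cells, 71 in microglia and 63 in monocytes or macrophages, and of 100 changed 4-fold it recovered 94, 99 and 95. It called 13, 9 and 13 unchanged genes, in fits of 12476, 10028 and 11824 genes that include the changed ones. Counts of different genes were drawn independently, so these numbers do not apply where genes move together. A first simulation with gene-wise spread called more unchanged genes and was replaced after its result was seen. The list step placed 4.0% (T cells) and 4.5% (monocytes or macrophages) of 200 random lists outside the percentiles and recovered 20 of 20 shifted lists at a log2 shift of 0.3. Genes varied independently in that simulation, so the rate does not apply to lists whose genes move together.

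As checks, Xist had 1 to 8 UMIs per library and the Y-linked gene Ddx3y 2571 to 7724, so every library came from male mice. Haemoglobin gene Hbb-bs had 271 UMIs in the normal water library of the live-cell sort, 43 in its high glucose partner and 0 to 3 elsewhere. Alternatives tried were other filters (500 genes, 20% mitochondrial UMIs, no doublet removal), resolution 2, clusters made in each library alone, T cells gated by at least 2 receptor UMIs, TMM factors, shares without thinning, a minimum of 100 UMIs per gene, RLE size factors, no expression filter, no pair term, each pair left out in turn, and the DESeq2 Wald test (DESeq2 1.42.0). Under the other filters the cells were clustered anew. All alternative clusterings were named from marker scores alone, without the rules on the runner-up and on leading genes. CPM totals without the repeat-derived genes Gm42418, AY036118 and Lars2 were added after seeing the data.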

Results

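Single-cell transcriptomes were collected from GL261 gliomas of mice that differed in sugar intake, gut colonisation and antibody treatment. SPF mice drank normal water or water with 20% dextrose from 5 weeks before inoculation until 2 weeks after it. Cells were isolated on day 20, and whether dextrose was given until then is not given in the sources used here. This pair of diets was sequenced 3 times: as CD45.2-sorted immune cells, as CD45.2-sorted cells of mice given 200 µg of an anti-PD-1 antibody on days 9, 12 and 15, and as all viable cells. Germ-free mice were gavaged with Desulfovibrio vulgaris, a sulfate-reducing gut bacterium, or with DPBS as the vehicle 3 times a week, starting 2 weeks before inoculation. Each of the 8 groups is 1 library of 3 pooled mice.

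The CD45.2-sorted diet libraries held 80683152 UMIs (normal water) and 78696976 (high glucose), and 6624 and 7051 cells were kept at medians of 8996 and 8034 UMIs per cell. The germ-free libraries were smaller, with 18944485 UMIs and 2369 cells for DPBS and 35553198 UMIs and 4735 cells for D. vulgaris. Their medians were 6910 and 5559 UMIs per cell. The anti-PD-1 libraries held 86304544 UMIs in normal water and 76482471 in high glucose, with 10029 and 9576 cells at medians of 6771 and 6421.5. The live-cell libraries held 58516604 and 45078935 UMIs, with 7285 and 4847 cells at medians of 4975 and 6328.

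The cells fell into 37 clusters, named as T cells, NK cells, B cells, dendritic cells (DC), monocytes or macrophages, microglia, neutrophils, mast cells or basophils, and endothelial or mural cells. Of 3 clusters left unnamed, 1 with 228 and 274 cells in the live-cell libraries carried the neural and glial precursor genes Sox2, Sox10, Olig1 and Nes at 177, 228, 398 and 219 CPM and the leukocyte gene Ptprc at 18.6 CPM. It was left unnamed because its leading genes held more markers of another class. It is called the glioma-marker cluster here for these genes alone: no label marks tumour cells, and its identity is uncertain. Both this cluster and the endothelial cells held at most 1 cell in each CD45.2-sorted library. All percentages of classes are of the immune cells of a library.

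**Figure D1:**
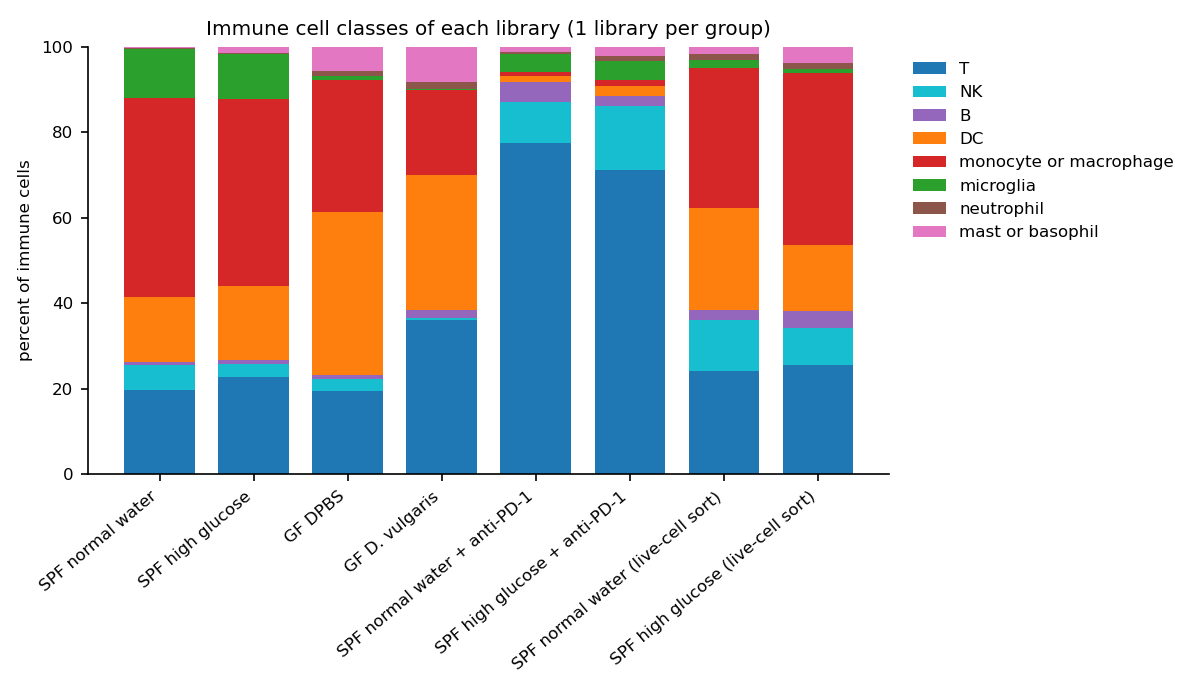
Share of each immune cell class (percent of immune cells, y axis) in the 8 libraries (x axis), 1 stacked bar per library. T cells made up 77.5% and 71.3% of the anti-PD-1 libraries and 19.5% to 36.1% of the other 6, and monocytes or macrophages 0.822% and 1.44% against 19.8% to 46.4%.

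The first comparison asked how 20% dextrose changed the immune infiltrate of SPF mice. With high glucose the T-cell compartment was tilted towards CD8 cells. T cells made up 22.7% of immune cells against 19.7% with normal water (ratio 1.16, interval 1.06 to 1.27), and the share of T cells in the CD8 gate was 54.5% against 34.0% (ratio 1.60, 1.42 to 1.82). The CD4 gate held 20.8% against 31.7% (ratio 0.659), and Foxp3, the transcription factor of regulatory T cells, was seen in 6.40% against 10.6% of T cells (ratio 0.605, 0.421 to 0.869). NK cells made up 3.10% against 5.88% (ratio 0.526, 0.417 to 0.662) and mast cells or basophils 1.39% against 0.272% (ratio 5.11, 2.63 to 10.5), while monocytes or macrophages were at 43.9% against 46.4%, DC at 17.3% against 15.4% and microglia at 10.5% against 11.6%.

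Within T cells the chemokine gene Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) was at 3208 CPM with high glucose against 1653 CPM, a log2 fold of 0.96. The receptor constant gene Trbc1 was at 807 against 422 CPM (log2 fold 0.94), Cd8a at 671 against 439 CPM (0.61), granzyme gene Gzmk at 76.8 against 51.2 CPM (0.59), the exhaustion regulator Tox at 130 against 87.2 CPM (0.57) and the checkpoint receptor gene Pdcd1 at 295 against 219 CPM (0.43). Of the 23 genes of the Th1 and cytotoxic effector list 14 were higher and 9 lower, and the median log2 fold of 0.13 lay at the 100th percentile of random lists, although the mean was 0.02. Its members did not move together: Gzma was at 1249 against 2146 CPM (-0.78), Ifng, the interferon-gamma gene, at 411 against 530.5 CPM (-0.37), Gzmb at 2111 against 2098 CPM (0.01) and the perforin gene Prf1 at 245 against 194 CPM (0.33). All 14 regulatory T genes were lower (median -0.69, percentile 0), among them Il10 at 26.4 against 63.0 CPM (-1.25) and Itgb8, which activates TGF-beta, at 15.7 against 33.0 CPM (-1.07). The growth factor gene Areg was at 43.3 against 108 CPM (-1.32). Of 14 naive or memory genes 12 were lower (median -0.38). Glycolysis genes had a median of -0.12 (15 of 20 lower), oxidative phosphorylation genes 0.06 (28 of 35 higher, Ndufa4 0.35) and proliferation genes 0.08 (19 of 23 higher).

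The share of T cells with an Ifng UMI was 26.9% against 29.3% after thinning (ratio 0.919, 0.774 to 1.09) and 57.6% against 50% without thinning (ratio 1.15). Gzmb was seen in 57.9% against 49.6% (ratio 1.17). In microglia thinned alike, the background shares with normal water and high glucose were 1.23% and 1.29% for Ifng, 4.09% and 4.02% for Gzmb, 0.273% and 0.287% for Foxp3, 0.409% and 1.44% for Cd8a, and 1.09% and 0.431% for Cd4. Median depths before thinning to 1500 UMIs were 8181.5 and 7907.5 UMIs in T cells and 8567 and 7742 in microglia. Within CD8-gated T cells Tox was at 107 against 46.0 CPM (log2 fold 1.21), Ifng had a log2 fold of -0.17 and Gzmb of -0.24.

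**Figure D2:**
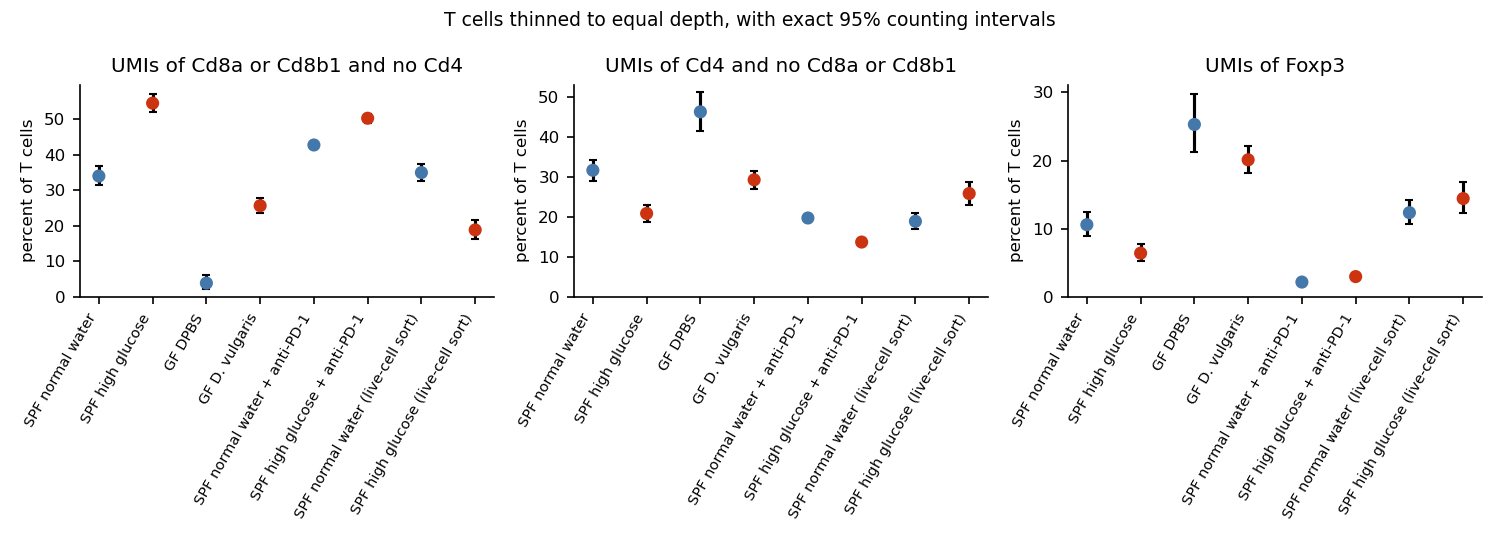
Percent of T cells (y axis) in the CD8 gate, in the CD4 gate and with a Foxp3 UMI in each of the 8 libraries (x axis), after thinning to 1500 UMIs per cell. Blue points are normal water or DPBS and red points high glucose or D. vulgaris. Bars are exact 95% intervals of counting error. The CD8 gate was higher with high glucose in the CD45.2 sort (54.5% against 34.0%) and lower in the live-cell sort (18.8% against 35.0%).

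In microglia Spp1, the osteopontin gene, and Lpl, the lipoprotein lipase gene, were higher with high glucose, at 465 against 106 CPM (log2 fold 2.13) and 173 against 73.2 CPM (1.24), and Arg1, an arginine-degrading enzyme, was at 79.2 against 14.6 CPM (2.43). All 23 proliferation genes were higher (median 0.82), including Ccna2 at 19.2 against 7.23 CPM (1.39) and Cenpe at 37.9 against 14.5 CPM (1.38). Inflammatory cytokine and NF-kB target genes were lower in 18 of 23 cases (median -0.28, percentile 0), for example Tnf at 103 against 157 CPM (-0.60) and Il12b (-0.89), while Il6 had 39 against 19 UMIs (1.23). The 20 dissociation and immediate early genes, which respond to tissue handling, were all lower in these microglia (median -0.33), with Fos at 601 against 870 CPM (-0.53). Homeostatic microglia genes were higher in 15 of 18 cases (median 0.11), with Fcrls at 462 against 294 CPM (0.65), P2ry12 at a log2 fold of 0.08, Tmem119 at 0.04 and Apoe at -0.40. MHC class II genes had a median of -0.11 (9 of 14 lower), with Cd74 at 5720 against 7329 CPM (-0.36).

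In monocytes or macrophages all 29 type I interferon response genes were higher (median 0.18, percentile 100), with Ifi44 at 52.1 against 39.9 CPM and Cmpk2 both at a log2 fold of 0.39. The interferon-stimulated cluster of this class, with Cxcl10 and Rsad2, made up 4.03% of kept cells against 1.81%. A change within clusters was not separated from this difference in shares. The alternative-activation gene Retnla was at 231 against 52.7 CPM (2.13). The neutrophil and inflammatory monocyte genes S100a9, Saa3 and S100a8 were at 15.9 against 52.2 CPM (-1.71), 26.3 against 81.1 CPM (-1.63) and 49.3 against 140 CPM (-1.51). Inflammatory cytokine genes were lower in 17 of 24 cases (median -0.14), including Il1b at 1840 against 2377 CPM (-0.37). The interferon-gamma response list had a median of 0.02, with Cxcl9 at -0.16, Cxcl10 at -0.11 and the PD-L1 gene Cd274 at -0.11. In DC, type I interferon and interferon-gamma genes were higher in 26 of 29 and 24 of 26 cases (medians 0.14 and 0.13), for example Irf7 at 446 against 332 CPM (0.43), and Cd40 was at 92.2 against 73.5 CPM (0.33), while Il12b was at 16.7 against 33.9 CPM (-1.02). In NK cells glycolysis genes were lower in 14 of 19 cases (median -0.13), with the glucose transporter gene Slc2a1 at -0.73. In microglia 5 of 6 genes of neutrophil RNA were lower (median -2.64), with Retnlg at 2 against 94 UMIs and S100a8 at 8 against 200 UMIs.

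The second comparison asked what D. vulgaris did in mice without other gut bacteria. The T-cell share of immune cells was 36.1% after D. vulgaris and 19.5% after DPBS (ratio 1.86, 1.64 to 2.10). CD8 cells were scarce in the DPBS library: 3.86% of T cells were in the CD8 gate, against 25.7% after D. vulgaris (ratio 6.66, 3.8 to 12.6). The CD4 gate held 29.3% against 46.3% (ratio 0.632) and Foxp3 was seen in 20.1% against 25.3% of T cells (ratio 0.795, 0.610 to 1.05, which includes 1). Monocytes or macrophages made up 19.8% against 30.9% (ratio 0.642, 0.570 to 0.723), DC 31.6% against 38.2% (ratio 0.826), NK cells 0.508% against 2.79% (ratio 0.182, 0.0921 to 0.349) and mast cells or basophils 8.15% against 5.63% (ratio 1.45).

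In T cells Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) was at 333 against 28.4 CPM, a log2 fold of 3.53, Cd8b1 at 233 against 25.6 CPM (3.16), Gzmk at 24.0 against 2.33 CPM (3.11, from 211 and 5 UMIs) and Ccl5 at 754 against 199 CPM (1.92). Of the Th1 and cytotoxic effector genes 14 of 23 were higher (median 0.19), with Ifng, Gzmb, Ccl3 and Ccl4 among those that were lower: Ifng was at 547 against 954 CPM (-0.80), Gzmb at 622 against 1048 CPM (-0.75), Ccl3 at 237 against 581 CPM (-1.29) and Ccl4 at 930 against 1697 CPM (-0.87). Of the regulatory T genes 13 of 14 were lower (median -0.66), including Il10 at 170 against 483 CPM (-1.51), and the cytokine gene Csf2 was at 53.3 against 205 CPM (-1.94). Oxidative phosphorylation genes were higher in 31 of 35 cases (median 0.30), with Cox5b at 165 against 103 CPM (0.67), and proliferation genes in 18 of 23 (median 0.39), with Ube2c at 45.1 against 11.2 CPM (1.96). Type I interferon genes were lower in 20 of 29 cases (median -0.23), with Rsad2 at 83.6 against 157 CPM (-0.91), and glucocorticoid response genes in 10 of 12 (median -0.47), with Dusp1 at 596 against 1058 CPM (-0.83). Prf1, Pdcd1 and Tox had log2 folds of 0.02, 0.07 and -0.22, and Txnip, Hk2, Ldha and Slc2a1 of 0.17, -0.83, -0.23 and -0.71. The regulatory T list was taken over all T cells, of which the CD8 gate held a larger share after D. vulgaris. Within CD4-gated T cells Foxp3 was at 234 against 222 CPM (0.075). The T-cell cluster with Foxp3 and Il2ra made up 15.1% of kept cells after D. vulgaris against 11.1%.

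The share of T cells with an Ifng UMI was 24.0% after D. vulgaris against 21.2% after DPBS (ratio 1.13, 0.862 to 1.51), and 36.2% against 27.0% without thinning. Gzmb was seen in 33.6% against 39.5% (ratio 0.851, 0.7045 to 1.035). Both of these intervals after thinning include 1. Microglia were too few for a background share: none of 12 cells of the DPBS library had a UMI of Ifng, Gzmb, Foxp3, Cd4 or Cd8a, which allows a share of up to 25%, and none of 15 cells of the D. vulgaris library had a UMI of Ifng, Gzmb or Foxp3, which allows up to 20.0%, while Cd4 and Cd8a were each seen in 6.67%. Median depths before thinning were 3910 and 4344.5 UMIs in T cells and 1974 and 2555 in microglia.

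In monocytes or macrophages 24 of 27 interferon-gamma response genes were lower after D. vulgaris (median -0.48, percentile 0), including the guanylate-binding gene Gbp8 at 6.35 against 14.8 CPM (-1.20), Nos2 with 1 against 20 UMIs, the T-cell attracting chemokine genes Cxcl10 at 1881 against 2694 CPM (-0.52) and Cxcl9 (-0.26), and Cd274 (-0.49). The interferon-stimulated cluster with Cxcl10 and Rsad2 made up 9.78% of kept cells against 17.9%. A change within clusters was not separated from this difference in shares. The complement gene C1qc was at 12.9 against 51.8 CPM and the matrix protease gene Mmp14 at 20.8 against 73.0 CPM (-1.80). Cd209a, a lectin of monocyte-derived cells, was at 156 against 66.3 CPM (1.23), and proliferation genes were higher in 16 of 17 cases (median 0.38), with Stmn1 at 11.8 against 1.83 CPM (2.57). Oxidative phosphorylation genes were higher in 32 of 35 cases (median 0.16). H2-Ab1, Arg1 and Il1b had log2 folds of -0.01, 0.10 and -0.14. In DC 19 of 26 interferon-gamma response genes were lower (median -0.20), with Socs1 at 74.1 against 113 CPM (-0.60), whereas Il12b, the interleukin-12 subunit gene, had 207 against 3 UMIs (14.4 against 0.332 CPM).

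The third comparison repeated the diet pair under anti-PD-1. T cells dominated both libraries, at 71.3% with high glucose against 77.5% with normal water (ratio 0.920, 0.899 to 0.942). NK cells made up 14.8% against 9.69% (ratio 1.53, 1.37 to 1.71), B cells 2.43% against 4.62% (ratio 0.527, 0.422 to 0.655), DC 2.37% against 1.51% (ratio 1.57, 1.17 to 2.10), monocytes or macrophages 1.44% against 0.822% (ratio 1.75, 1.19 to 2.59) and mast cells or basophils 2.14% against 1.10% (ratio 1.94, 1.40 to 2.70). The CD8 gate held 50.3% against 42.8% of T cells (ratio 1.18, 1.12 to 1.24), the CD4 gate 13.7% against 19.7% (ratio 0.695) and Foxp3 was seen in 2.96% against 2.16% (ratio 1.37). Ifng was seen in 23.5% against 27.6% (ratio 0.853, 0.787 to 0.924) and Gzmb in 32.9% against 30.0% (ratio 1.10). Background shares in microglia with normal water and high glucose were 2.07% and 2.30% for Ifng, 2.84% and 1.28% for Gzmb, 2.07% and 0.255% for Cd8a, and for Foxp3 0.517% and 0 of 392 cells, which allows up to 0.765%. Median depths before thinning were 7301.5 and 6992 UMIs in T cells and 5876 and 6303 in microglia.

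In T cells of the high-glucose library naive or memory genes were higher in 13 of 14 cases (median 0.29, percentile 99.95), with Tcf7, a factor of memory and stem-like T cells, at 57.3 against 35.4 CPM (0.69) and Bach2 at 221 against 144 CPM (0.61). Proliferation genes were lower in 22 of 23 cases (median -0.37), with Ube2c at 7.33 against 17.3 CPM (-1.24), and all 35 oxidative phosphorylation genes were lower (median -0.21). Glycolysis genes were lower in 14 of 20 cases (median -0.13), with Gapdh at 504 against 675 CPM (-0.42). Trbc1 was at 343 against 987 CPM (-1.53), the histone gene Hist1h2ap at 30.1 against 80.8 CPM (-1.42), Smad3 at 57.6 against 30.8 CPM (0.90) and Camk1d at 2702 against 1479 CPM (0.87). Prf1 was at 195 against 137 CPM (0.51), Tox at 582 against 436 CPM (0.42), Gzmb at 807 against 681 CPM (0.25), Ifng at 315 against 407 CPM (-0.37) and Pdcd1 at a log2 fold of -0.03. The Th1 and cytotoxic effector list had a median of -0.07 (percentile 8.15). All 10 genes of myeloid RNA in lymphocytes were lower (median -0.84). In this pair genes with the most intron sequence were higher relative to genes with no intron, by a log2 difference of 0.32 in T cells, 0.34 in NK cells and 0.21 in microglia, against -0.02, -0.03 and 0.02 in the pair without antibody. That difference is of the size of the medians of the naive or memory list, which holds long genes such as Bach2, and of the oxidative phosphorylation list.

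In NK cells 25 of 28 type I interferon genes were lower with high glucose (median -0.40), with Ifit1 at 8.75 against 23.5 CPM (-1.41) and Isg15 at 37.1 against 73.3 CPM (-0.98). In the 137 and 82 monocytes or macrophages type I interferon genes were higher in 20 of 28 cases (median 0.19) and interferon-gamma genes in 20 of 24 (median 0.14), with Cxcl9 at 775 against 274 CPM (1.49), Iigp1 at 121 against 34.9 CPM (1.73) and H2-Ab1 at 206 against 75.1 CPM (1.43). In DC interferon-gamma genes were higher in 21 of 26 cases (median 0.22), with Cxcl9 at 829 against 535 CPM (0.63). In microglia Spp1 was at 125 against 50.3 CPM (1.30) and Lpl at 59.7 against 29.0 CPM (1.03), as in the pair without antibody. All 13 MHC class II genes were lower there (median -0.34), with H2-Eb1 at 638 against 1013 CPM (-0.67), and inflammatory cytokine genes were lower in 14 of 21 cases (median -0.34), with Ccl2 at 52.7 against 145 CPM (-1.46) and Cxcl2 with 4 against 36 UMIs. Dissociation genes were also lower there in 17 of 20 cases (median -0.24).

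The fourth comparison took the diet pair without a CD45.2 sort, so that vascular cells and, per the labels, tumour cells were captured too. Monocytes or macrophages made up 40.3% of immune cells with high glucose against 32.7% (ratio 1.23, 1.14 to 1.33), DC 15.3% against 24.0% (ratio 0.639, 0.567 to 0.720), NK cells 8.63% against 11.9% (ratio 0.726, 0.610 to 0.862), B cells 4.10% against 2.35% (ratio 1.74, 1.27 to 2.40), mast cells or basophils 3.76% against 1.65% (ratio 2.28, 1.59 to 3.26) and T cells 25.5% against 24.2% (ratio 1.06, 0.957 to 1.17). The CD8 gate was smaller with high glucose, 18.8% against 35.0% of T cells (ratio 0.538, 0.436 to 0.662), and the CD4 gate larger, 25.8% against 18.9% (ratio 1.37). The delta receptor gene Trdc was seen in 12.2% against 3.83% of T cells (ratio 3.17, 2.04 to 4.99) and Ifng in 13.5% against 21.6% (ratio 0.624, 0.476 to 0.813). Gzmb was seen in 26.3% against 37.3% (ratio 0.704) and Foxp3 in 14.4% against 12.4% (ratio 1.17, 0.8625 to 1.578, which includes 1). In 118 microglia of the normal water library the background shares were 0.848% for Ifng, Gzmb, Foxp3 and Cd4, with no UMI of Cd8a or Trdc (up to 2.54%), and none of 32 microglia of the high-glucose library had a UMI of these genes or of Trdc, which allows up to 9.38%. Median depths before thinning were 3885.5 and 5514 UMIs in T cells and 5217 and 7815.5 in microglia.

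In T cells Trdc was at 155 against 32.0 CPM (2.27), Tcrg-C1 at 51.5 against 13.5 CPM (1.92), Cd8a at 198 against 388 CPM (-0.97), Cd4 at 284 against 178 CPM (0.67), Foxp3 at 152 against 103 CPM (0.56) and Ifng at 384 against 502 CPM (-0.39). The choroid plexus gene Ttr was at 419 against 6.34 CPM (6.02). Type I interferon genes were higher in 23 of 29 cases (median 0.32), with Ifi44 at 1.20 and Slfn5 at 84.6 against 50.3 CPM (0.75). Exhaustion genes were lower in 14 of 16 cases (median -0.30), with the inhibitory receptor gene Cd160 at 10.7 against 31.6 CPM (-1.55), all 23 proliferation genes were lower (median -0.54), and T-cell receptor signalling genes were higher in 13 of 16 cases (median 0.16). The Th1 and cytotoxic effector list had a median of -0.14 (percentile 19.1). In CD8-gated T cells Ifng was at 175 against 445 CPM (-1.34) and Tox at -1.25.

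In monocytes or macrophages of this pair the suppressive tumour macrophage genes were higher in 16 of 19 cases (median 0.33), with Arg1 at 2249 against 617 CPM (1.87), Mrc1 at 614 against 267 CPM (1.20) and Cd163 with 100 against 8 UMIs. Glycolysis genes were higher in 19 of 20 cases (median 0.39), with Hk2 at 318 against 196 CPM (0.70), and hypoxia genes in 16 of 20 (median 0.48), with Ero1l at 190 against 97.4 CPM (0.96). The chemokine genes Ccl7 and Cxcl2 were at 374 against 60.2 CPM (2.64) and 1839 against 778 CPM (1.24). Interferon-gamma response genes were lower in 21 of 27 cases with a median of -0.20 that lay inside the random range (percentile 23.3), and Cxcl10 was at 522 against 901 CPM (-0.79). The collagenase gene Mmp13 was at 21.7 against 146 CPM (-2.75) and the heat-shock gene Hspa1b at 175 against 748 CPM (-2.09), and 19 of 20 dissociation genes were lower (median -0.32). The median log2 fold of all genes was -0.16 in this class, -0.10 in DC and -0.05 in T cells, and the repeat-derived gene Gm42418 took 15.7% against 7.10% of UMIs in monocytes or macrophages and 12.8% against 6.29% in T cells. Relative to that shift the interferon-gamma median is -0.04 with TMM factors.

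In the glioma-marker cluster, which is not known to be glioma, the secretory granule gene Chga had 733 UMIs with high glucose and 0 with normal water (at least 538-fold higher), and the hormone genes Cck and Cga 413 and 177 against 0 (at least 303-fold and 130-fold higher). The imprinted growth gene H19 was at 11.4 against 126 CPM (-3.42) and the adhesion gene Pcdh15 at 39.2 against 171 CPM (-2.12). Interferon-gamma response genes were lower in 23 of 25 cases (median -0.84, percentile 0), with Irf1 at 109 against 317 CPM (-1.53). Proliferation genes were higher in 18 of 23 cases (median 0.23), with Ccnb1 at 51.7 against 16.6 CPM (1.64). Glycolysis and oxidative phosphorylation genes had medians of 0.15 and 0.13 (percentiles 99.3 and 99.8), with Gapdh at 1482 against 908 CPM (0.71), and glucose-responsive genes a median of 0.15, although Txnip, which glucose induces, was at 64.6 against 141 CPM (-1.12). Of the dissociation genes 17 of 20 were lower (median -0.56), with Egr1 at 670 against 1788 CPM (-1.42).

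**Figure D3:**
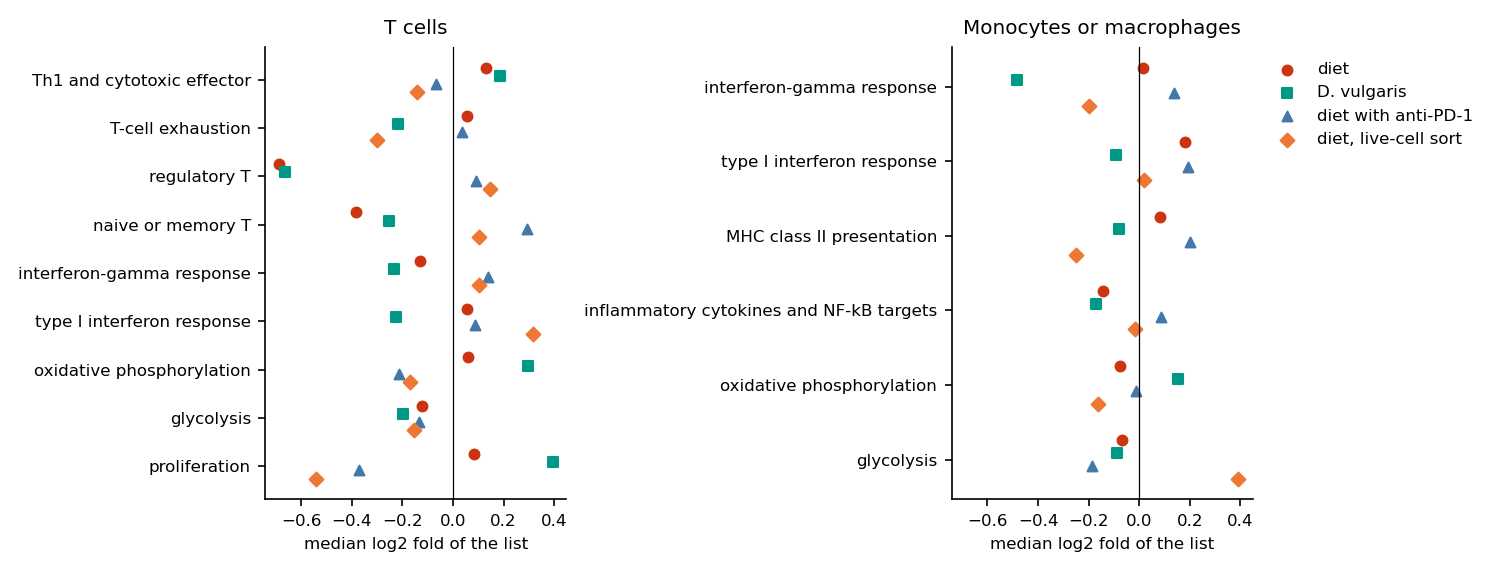
Median log2 fold of the members of fixed gene lists (x axis) in T cells (left) and in monocytes or macrophages (right), for the 3 diet pairs (high glucose over normal water) and the germ-free pair (D. vulgaris over DPBS), 1 point per pair. The regulatory T list sits at -0.69 and -0.66 in the diet and germ-free pairs of the CD45.2 sort and at 0.09 and 0.15 in the other 2.

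The fifth and sixth comparisons set anti-PD-1 against no antibody at each diet. Antibody was not the only difference: Cell Ranger 6.1.2 wrote the libraries with antibody and 5.0.0 those without. The antibody also goes with the experiment, so differences in class shares cannot be ascribed to it alone. The intervals cover counting error only. T cells were 3.94 times as large a share of immune cells with anti-PD-1 in normal water (3.71 to 4.18) and 3.14 times in high glucose (2.96 to 3.32). Monocytes or macrophages had ratios of 0.0177 (0.0137 to 0.0225) and 0.0327 (0.0268 to 0.0396), DC of 0.0983 and 0.137, microglia of 0.364 and 0.422, NK cells of 1.65 and 4.79, and B cells of 7.27 and 2.81. Foxp3 was seen in 2.16% of T cells with the antibody against 10.6% without in normal water (ratio 0.204), and in 2.96% against 6.40% in high glucose (ratio 0.463). The cycling gene Mki67 was seen in 5.20% against 16.4% (ratio 0.318) and 3.99% against 15.2% (ratio 0.262), with ratios of 0.461 and 0.409 without thinning. It was also seen in 5.87% and 8.91% of microglia without antibody and 0.258% and 0.765% with it. Microglial background shares of Foxp3 and the depths are those given above for these 4 libraries.

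Genes with long introns set the anti-PD-1 libraries apart in every class measured. In T cells Cmss1 was at 6490 and 8786 CPM with anti-PD-1 and at 9.65 to 14.1 CPM in the other 6 libraries, and Camk1d at 1479 and 2702 against 17.6 to 40.9 CPM. Il31ra had 9541 UMIs against 1 in normal water, and in high glucose 10484 against 0, at least 1150-fold higher, and Fgfr2 was at least 222-fold higher in normal water. Over the tenth of genes with the most intron sequence (at least 88471 bases) the median log2 fold in T cells was 1.37 in normal water and 1.79 in high glucose, against -0.58 and -0.65 for genes with no annotated intron, and NK cells and microglia had differences of 2.04 to 2.54. The values of single genes and lists in these comparisons carry this difference. T cells of the anti-PD-1 libraries lay mainly in clusters 1, 3, 7, 8, 19, 26, 31 and 35, which held at most 4 cells of any other library, and those without antibody in clusters 6, 9, 12 and 16. Microglia lay mostly in cluster 23 with and in cluster 11 without antibody, while cluster 34 held microglia of both (34 and 39 cells with, 41 and 69 without). NK cells lay almost all in cluster 5 with and in cluster 10 without antibody, and B cells mostly in cluster 27 with and in cluster 28 without.

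**Figure D4:**
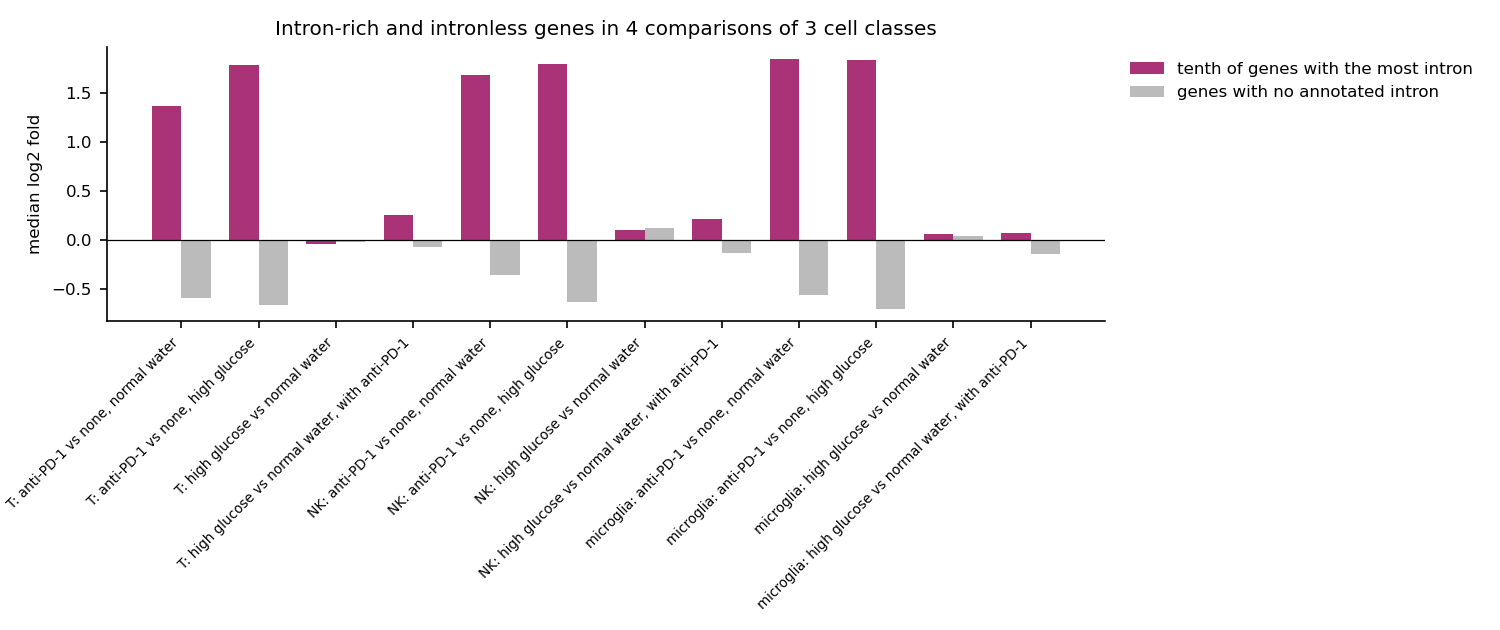
Median log2 fold (y axis) of the tenth of genes with the most intron sequence and of genes with no annotated intron, in T cells, NK cells and microglia, for anti-PD-1 over none at each diet and for high glucose over normal water without and with anti-PD-1 (x axis), 1 bar per median. In the antibody comparisons the paired bars differ by 1.95 to 2.54.

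With that limit, T cells with anti-PD-1 in normal water had Gzmb at 681 against 2098 CPM (-1.62), Foxp3 at 13.5 against 82.0 CPM (-2.60), Tox, a gene with long introns, at 436 against 87.2 CPM (2.32), Il12rb2, the interleukin-12 receptor subunit, at 246 against 43.4 CPM and Ifng at a log2 fold of -0.38. In high glucose Gzmb, Foxp3, Tox and Ifng had log2 folds of -1.39, -1.43, 2.17 and -0.38. Th1 and cytotoxic effector genes had medians of 0.46 (percentile 99.5) and 0.22 (94.5), regulatory T genes -1.18 and -0.55, and all 23 proliferation genes were lower at both diets (medians -2.43 and -2.84). Oxidative phosphorylation, which consists of short genes, had medians of -0.66 and -0.98, the unfolded protein response -1.10 at both diets, and naive or memory genes -0.01 and 0.89. All 10 genes of myeloid RNA in T cells were lower (medians -3.12 and -4.23), with Apoe at -4.29 and -5.46, beside the lower myeloid share of these libraries. In NK cells Ccl5 was at 7626 against 1204 CPM (2.66) and Gzmb at 786 against 3153 CPM (-2.01) in normal water.

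Microglia with anti-PD-1 had all 29 type I interferon genes lower (medians -1.70 in normal water and -2.03 in high glucose), 19 and 20 of 20 disease-associated microglia genes lower (medians -1.90 and -1.77), with Apoe at 2028 against 11260 CPM (-2.47) in normal water, and all proliferation genes lower, with Mki67 at 2.45 against 66.4 CPM (-4.54). The homeostatic receptor gene P2ry12 was at 1355 against 562 CPM (1.27) and had a log2 fold of 1.05 in high glucose. P2ry12 spans 59216272 to 59262871 on chromosome 3, and its rise was not separated from the intron difference given above. The 82 and 137 monocytes or macrophages of the antibody libraries had far lower macrophage genes than the other 2: C1qb was at 3.49 against 2533 CPM (-8.92) in normal water, Arg1 was at least 134-fold lower and in high glucose at least 305-fold lower, and H2-Ab1 was at -6.40 and -5.14. Suppressive macrophage genes had medians of -2.29 and -2.70 and MHC class II genes of -2.87 and -2.42. Cluster 20, with Ace, held 68 and 109 of these cells, and clusters 0 and 2, which held most of this class without antibody, at most 1 each. The median of all genes in this class was 0.21 in normal water. In DC interferon-gamma genes were higher in 18 of 26 cases at both diets (medians 0.41 and 0.51), with Cxcl10 at 709 against 192 CPM (1.89) in normal water.

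The diet effect over all 3 SPF pairs was tested gene by gene, with the pairs as replicates (n = 3 pairs). The SE and p-values rest on a spread moderated over genes and do not measure the spread of a gene between the pairs. In microglia 12 of 10222 genes passed the edgeR test, 5 higher and 7 lower with high glucose. DESeq2 still called 2 of the 12, and edgeR 6 of the 12 with doublets kept, not Tnf (-0.57) or Ccl4 (-0.54). Lpl, the lipoprotein lipase gene (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), rose by a log2 fold of 1.09 ± 0.13 (SE, adjusted p = 0.000188) and was higher in every pair (1.24, 1.03 and 0.87 in the CD45.2 sort, with anti-PD-1 and in the live-cell sort). In the high-glucose libraries 10 cells held 42.2%, 70.3% and 96.6% of the Lpl UMIs. The share of cells with a UMI was 27.97% against 22.7% in the CD45.2 sort, 8.98% against 8.08% with anti-PD-1 and 31.6% against 17.3% in the live-cell sort. The chemokine genes Ccl6 and Ccl24 rose by 0.76 ± 0.13 and 1.00 ± 0.19 (adjusted p = 0.0264 and 0.0400 by edgeR). For Ccl6, 10 cells held 39.9% of the UMIs in the high-glucose CD45.2 library and 17.8% with normal water, and 35.7% against 36.4% of cells had a UMI. With anti-PD-1 25.3% against 21.6% of cells had a Ccl6 UMI, and in the live-cell sort 44.7% against 19.7%. For Ccl24, 10 cells held 66.4% of the 575 UMIs in the high-glucose CD45.2 library, 22.6% of cells had a UMI against 24.3% with normal water, and the anti-PD-1 pair had 12 against 11 UMIs. In the live-cell sort 15.8% against 6.30% of cells had a Ccl24 UMI, with 22 against 20 UMIs. Among the lower genes, Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) had a log2 fold of -0.78 ± 0.12 (adjusted p = 0.0111 by edgeR), Tnf of -0.66 ± 0.12 (0.0349), Ccl4 of -0.61 ± 0.11 (0.0349), Ccrl2 of -0.66 ± 0.13 (0.0400), the phosphatase gene Dusp2 of -0.82 ± 0.15 (0.0285) and the transcription factor gene Cebpb of -0.74 ± 0.14 (0.0349), each lower in 3 of 3 pairs. The share of cells with a UMI did not follow throughout: in the live-cell sort it was 71.1% against 63.0% for Ccrl2 and 55.3% against 54.3% for Tnf. For Tnf with anti-PD-1 it was 16.3% against 16.4%, and for Il1b in the live-cell sort 52.6% against 52.8%. In the other cases of these lower genes the share was lower too. The live-cell folds rest on 38 high-glucose cells, with 8 against 53 UMIs of Dusp2. Pairs also differed: Cebpb was at -0.28, -0.87 and -1.31 in the CD45.2 sort, with anti-PD-1 and in the live-cell sort. Few cells carry Il1b in part of the data: 10 cells held 89.5% and 92.4% of its UMIs in the high-glucose and normal water libraries with anti-PD-1, and 10 of 38 cells held 89.5% in the high-glucose live-cell library. Mcpt1, a mast cell protease gene, passed at 1.90 ± 0.33 (adjusted p = 0.0280 by edgeR), but 10 cells held 93.9% of its 66 UMIs in the high-glucose CD45.2 library and it had 0 UMIs in both live-cell libraries. Arg1 (2.66 ± 0.18, adjusted p = 2.81e-08) and S100a9 (-2.94 ± 0.52, adjusted p = 0.0280) passed the edgeR test without 1 sign in all pairs, and Arg1 rests on 10 cells that held 82.0% of its 495 UMIs in the same library, with 0 against 1 UMI in the anti-PD-1 pair. All 169 and 66 S100a9 UMIs of the normal water CD45.2 and live-cell libraries lay in 10 and 4 microglia.

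**Figure D5:**
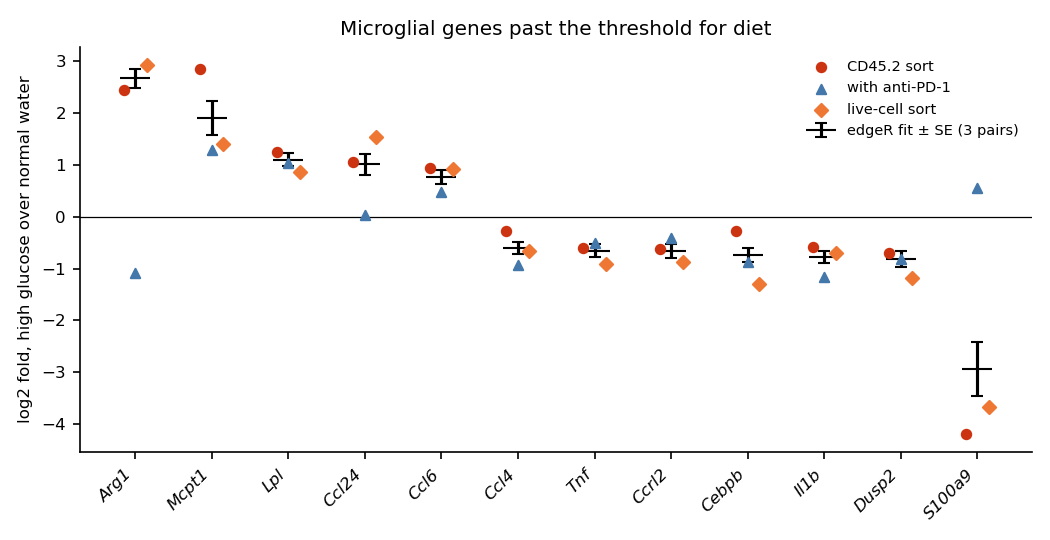
Log2 fold of high glucose over normal water (y axis) for the 12 microglial genes past the threshold (x axis): edgeR estimate with its standard error and the value of each pair. Lpl lies between 0.87 and 1.24 in the 3 pairs and Il1b between -1.17 and -0.59, while Arg1 and S100a9 differ in sign between pairs. The anti-PD-1 value of Arg1 rests on 0 against 1 UMI and the live-cell value of Mcpt1 on 0 UMIs.

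In monocytes or macrophages 4 of 12004 genes passed the edgeR test, 1 higher and 3 lower. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) fell with a log2 fold of -1.51 ± 0.17 (adjusted p = 0.00917), and S100a8 with -1.31 ± 0.17 (0.0270), each lower in 3 of 3 pairs. Wfdc21 fell with -2.65 ± 0.29 (0.0120), lower in 2 of 3 pairs and with 0 UMIs in both anti-PD-1 libraries. Few cells carry these genes: the 10 cells with the most held 98.8% of the 1541 S100a9 UMIs of the normal water CD45.2 library and 96.3% of its 4134 S100a8 UMIs, and the anti-PD-1 libraries had 3 and 2 S100a9 UMIs. The share of cells with a UMI did not follow the sums throughout: it was 1.36% with high glucose against 0.913% for S100a9 in the CD45.2 sort and 3.42% against 2.39% for S100a8 in the live-cell sort. With doublets kept, S100a8 and S100a9 had log2 folds of only -0.33 and -0.30 (adjusted p = 0.999 for both by edgeR) and Wfdc21 of -2.52 (0.236). Under that setting the cells were also clustered anew and the clusters named from marker scores alone. The calls thus depend on this setting, and the doublets were not separated from the new clusters and names. Rnase2a passed at 2.70 ± 0.19 (adjusted p = 0.000515 by edgeR), higher in 2 of 3 pairs and absent from the anti-PD-1 pair. Of the genes at least 1.5-fold apart in every pair that did not pass the edgeR test, Cbr2 had the largest fold, 1.86 (adjusted p = 0.0657), with 4 against 0 UMIs in the anti-PD-1 pair. Lpl, which rose in microglia, was lower here in each pair (-0.92, -0.59 and -1.97) with a fitted fold of -1.26 (adjusted p = 0.0583 by edgeR). Cxcl9, Cxcl10, Cd274, H2-Ab1 and Arg1 had fitted log2 folds of 0.41, -0.11, 0.00, 0.36 and 1.18, none past the threshold.

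In T cells no gene passed the edgeR test, with 621 of 12717 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0953, for the protease gene Adam12 (1.87 ± 0.26). DESeq2 called 14 higher and 5 lower, and edgeR with RLE size factors 15 higher and 2 lower. Ifng was lower in all 3 pairs by a near-equal amount (-0.37, -0.37 and -0.39) without passing (adjusted p = 0.879 by edgeR). Gzmb, Prf1, Foxp3, Pdcd1 and Cd8a had fitted folds of 0.01, 0.19, 0.01, 0.09 and -0.01. Among genes over 1.5-fold in every pair, Il17re, an interleukin-17 receptor gene, the desmosome gene Dsc2 and the kinase gene Blk had the highest folds, 2.09, 1.88 and 1.87 (adjusted p = 0.119, 0.855 and 0.119 by edgeR). In the CD45.2 pair Il17re had 10 against 3 UMIs and Blk 4 against 1, and in the live-cell pair Dsc2 had 2 against 0. The genes S100a2 and Aldoc, an aldolase gene, were among the lowest, -2.20 and -0.92 (0.294 and 0.266).

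Among class shares over the 3 pairs, the mean log2 ratio of mast cells or basophils was 1.498 (SD 0.75, n = 3, exact p = 0.25, the smallest possible), with 2.35, 0.96 and 1.19 in the single pairs. Different cells make up these values: basophils in the CD45.2 sort (96 against 11 cells) and the live-cell sort (140 against 106), and mostly mast cells with anti-PD-1 (179 against 110), which went the other way in the CD45.2 sort (2 against 7). Neutrophils had a mean of 0.44 (0.36, 0.91 and 0.06 in the pairs, exact p = 0.25). T cells had a mean of 0.06 (SD 0.17), monocytes or macrophages 0.34 (SD 0.44) and NK cells -0.26 (SD 0.79), with exact p values of 0.75, 0.50 and 0.75. Genes of 1 sign in all pairs were 24.3% in T cells, 26.9% in microglia and 30.4% in monocytes or macrophages, where chance gives 25%. Across genes, the T-cell folds of the first diet pair had a Pearson r of 0.26 (Spearman rho 0.23) with those of D. vulgaris, of -0.01 with the diet pair under anti-PD-1 and of -0.15 with the live-cell pair, while the other correlations of this kind lay between -0.17 and 0.28. Without 1 pair, the T-cell count was 34 higher and 23 lower (CD45.2 pair left out), 1 and 0 (anti-PD-1) or 0 and 3 (live-cell), the microglia count 9 and 11, 7 and 19 or 37 and 42, and the monocyte or macrophage count 68 and 39, 3 and 4 or 18 and 18.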

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

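The tests on nuclear RNA, Cell Ranger version, the response of T cells, tissue dissociation, neutrophils within the macrophage class and the splits of the libraries were chosen only after the result was seen. Several diet effects went opposite ways in the 3 SPF pairs, each with counting intervals away from 1 (for genes in T cells, after thinning). The differences between pairs were not tested, since each pair has 1 library per diet.

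The ratio of class shares, high glucose to normal water, was 1.157 for T cells in the CD45.2 sort and 0.9204 with anti-PD-1. For B cells it was 1.744 in the live-cell sort and 0.5265 with anti-PD-1. For NK cells it was 1.529 with anti-PD-1, 0.526 in the CD45.2 sort and 0.7258 in the live-cell sort. For DC it was 1.12 in the CD45.2 sort, 1.566 with anti-PD-1 and 0.6391 in the live-cell sort, and for monocytes or macrophages 1.748 with anti-PD-1, 1.233 in the live-cell sort and 0.9469 in the CD45.2 sort. Within T cells the CD8 gate had ratios of 1.604 (CD45.2 sort), 1.176 (anti-PD-1) and 0.5384 (live-cell sort), and the CD4 gate of 0.6585, 0.6946 and 1.368. Foxp3 had ratios of 0.605 in the CD45.2 sort and 1.372 with anti-PD-1, and Gzmb of 1.168 (CD45.2 sort), 1.098 (anti-PD-1) and 0.7035 (live-cell sort). Without thinning the ratio for Foxp3 with anti-PD-1 was 1.17 (0.962 to 1.43), and those for Gzmb were 1.07 (0.998 to 1.15) in the CD45.2 sort and 1.04 (0.988 to 1.09) with anti-PD-1, so these 3 intervals include 1.

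List medians in T cells also parted. The regulatory T list was at -0.687 in the CD45.2 sort and 0.147 in the live-cell sort, and the naive or memory list at -0.382 in the CD45.2 sort and 0.293 with anti-PD-1. The interferon-gamma response was at -0.131 in the CD45.2 sort and 0.103 in the live-cell sort. Oxidative phosphorylation was at 0.061 in the CD45.2 sort and -0.213 with anti-PD-1, and in microglia at 0.08 and -0.102. Proliferation was at 0.084 in the CD45.2 sort, -0.372 with anti-PD-1 and -0.541 in the live-cell sort. None of these differences between pairs was tested.

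Cmss1, Camk1d and other genes were far higher in T cells of both anti-PD-1 libraries than in the other 6. Over T cells, NK cells and microglia at both diets, genes with the most intron sequence exceeded genes with no intron by a log2 difference of at least 1.95, which is what counting of intronic reads in those 2 libraries alone would give. A response of T cells to the antibody alone is argued against by microglia, whose Cmss1 fold was at least 1.054 times that of T cells, nuclear RNA left by lost cytoplasm by Malat1, under 1.5-fold higher in 6 of 6 comparisons, and the Cell Ranger version by the other libraries of that version, whose highest Cmss1 ratio to the older version was 1.021. A counting option used for these libraries may therefore account for the intron-rich genes. The same genes lie within an antibody comparison, so for a single gene with long introns the antibody and the counting were not separated here.

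In microglia Il1b, Tnf, Ccl4 and other genes fell with high glucose over the 3 pairs. Monocytes or macrophages mixed into the class are argued against, since their markers within microglia had median log2 folds of 0.08, 0.02 and 0.28 (highest 0.281) rather than negative ones. An immediate early response to tissue dissociation cannot be told apart from an inflammatory one: the dissociation list fell short of the inflammatory list in 1 pair (ratio of medians 0.711) and exceeded it in the other (1.20), and the live-cell pair has 38 microglia in the high-glucose library. An effect of the diet on microglia stays open and may act beside handling. Of 10 splits of the 6 libraries, too few for a share under 0.05, only the real split gave 12 genes, and the highest other gave 8.

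S100a8 and S100a9 fell in monocytes or macrophages with high glucose, but with doublets kept their log2 folds were only -0.33 and -0.30, and why was not tested. Free neutrophil RNA is argued against by T cells, which had 0.00998, 0.110 and 0.0759 times as many of these UMIs per cell as monocytes or macrophages of the same normal water library (lowest 0.009981), and other shares of the macrophage clusters by the mean fold within clusters, which was -1.46 at its highest (-1.457). Neutrophils called as monocytes or macrophages cannot be told apart from a change within the class: the neutrophil gene Retnlg per S100a8 and S100a9 UMI was 0.00336 times that of neutrophils in the CD45.2 sort, 0 with anti-PD-1 (upper bound 2.20) and 0.852 in the live-cell sort. This test replaced a first one on other neutrophil markers, whose highest median log2 fold was -0.11, and conditions on the spread between quartiles were added to the tests after values were seen. Few cells carry the signal, with 97.9% of the UMIs in 31 of 3068 cells of the normal water CD45.2 library, so the animals or a small population may explain it.

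For the other counts of genes past the threshold, 10 splits are again too few for a share under 0.05. In T cells the real split gave 0 genes and the highest other 2, so all 10 splits gave as many, which a real count of 0 makes certain and which says nothing on chance. In monocytes or macrophages the real split gave 4 and the highest other 310, and 4 of the 10 splits, the real one among them, gave as many or more. The 310 genes came from both splits that keep the CD45.2 and anti-PD-1 pairs whole, so that only the 2 live-cell libraries are set against each other and the other pairs supply the spread. This points to a structure of the samples. Whether diet, the pools of mice or the preparation lies behind that was not tested. Other splits that part all 3 pairs gave at most 6.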

How the results depend on the processing

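Totals without repeat-derived genes were the only alternatives chosen after seeing the data. Of the values that answer a comparison, 132 were the same within their counting interval or within 1.5 times a count, and 54 moved. Among single genes 176 were the same, 26 moved, 48 no longer passed the test and 3 reversed, those given next. Of the named genes under TMM factors 909 were the same and 114 moved. No cause was tested unless stated.

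With TMM factors 3 small folds changed sign: Psmb8 in T cells under anti-PD-1 in normal water (0.04), Cd8a in CD8-gated T cells of the diet pair with anti-PD-1 (-0.009) and Cxcl9 in monocytes or macrophages of the live-cell pair (0.055). The T-cell ratio for anti-PD-1 in normal water was 3.634 with up to 20% mitochondrial UMIs and 3.138 with T cells gated by UMIs, and 2.601 with that gate in high glucose. The Th1 and cytotoxic effector median was -0.154 (diet with anti-PD-1), -0.087 (live-cell) and 0.543 (anti-PD-1 in normal water) with TMM factors, 0.373 in the last with up to 20% mitochondrial UMIs, and without repeat-derived genes -0.033 (live-cell), 0.528 and 0.351 (anti-PD-1 in normal water and high glucose). The interferon-gamma median in monocytes or macrophages of the live-cell pair was -0.042 with TMM factors and -0.057 without repeat-derived genes, which took a larger share of UMIs there with high glucose, and -0.213 without them for anti-PD-1 in high glucose.

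Without thinning, cells differ in depth and the shallow cells are kept. The Ifng ratio was then 1.151 for diet and 1.104 for anti-PD-1 in normal water, so both crossed 1. Median T-cell depth was lower, not higher, in the high-glucose and antibody libraries of these comparisons, and why the ratios crossed was not tested. For anti-PD-1 in normal water and high glucose the ratios were 0.7262 and 0.7016 for Gzmb, 0.8158 and 0.8122 for Cd4, and 1.314 and 0.9613 for Cd8a.

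The counts of genes past the threshold for diet depended most on the choices (higher, lower with high glucose). In T cells (0, 0 in edgeR, with 621 genes at an unadjusted p under 0.05) they were 15 and 2 with RLE size factors, 61 and 50 without the expression filter, 14 and 5 with DESeq2, and 0 to 34 and 0 to 23 over leave-one-out fits. In microglia (5, 7) they were 4 lower with RLE size factors, 31 and 43 without the filter, 0 and 0 without the pair term, 3 lower without doublet removal, 1 and 1 with DESeq2, and 7 to 37 and 11 to 42 over leave-one-out fits. In monocytes or macrophages (1, 3) they were 89 and 69 without the filter, 0 and 0 without the pair term, 0 lower without doublet removal, and 3 to 68 and 4 to 39 over leave-one-out fits. Of the 12 microglial genes 8 were still called with RLE size factors, 12 without the filter, 6 without doublet removal, 2 with DESeq2 and 5, 9 and 12 without the CD45.2, anti-PD-1 or live-cell pair. Of the 4 macrophage genes 4 were still called with RLE size factors, without the filter and with DESeq2, 1 without doublet removal and 2, 4 and 4 without each pair. The leave-one-out fits have 1 residual degree of freedom fewer than the 2 of all pairs. Without the pair term the differences between antibody and sort enter the spread. The number of cells limits the 38 microglia of the high-glucose live-cell library, the 82 and 137 monocytes or macrophages with anti-PD-1 and the 12 and 15 thinned microglia of the germ-free libraries.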

Other observations

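The test of gamma-delta T markers was chosen only after the result was seen. Basophils stood out among the rarer cells. A cluster with Hdc, Mcpt8 and Gata2, genes of basophils, made up 1.36% of kept cells with high glucose against 0.166% with normal water in the CD45.2 sort, 2.89% against 1.46% in the live-cell sort, 0.261% against 0 of 10029 cells with anti-PD-1, and 8.09% against 5.57% after D. vulgaris. A cluster with the mast cell protease genes Mcpt2 and Tpsb2 made up 1.87% against 1.10% of the anti-PD-1 libraries and 0.0284% against 0.106% in the CD45.2 sort.

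Within monocytes or macrophages the interferon-stimulated cluster with Cxcl10 and Rsad2 made up 4.03% of kept cells with high glucose against 1.81% in the CD45.2 sort, 0.433% against 0.755% in the live-cell sort and 9.78% after D. vulgaris against 17.9%. The monocyte cluster with Chil3 made up 0.865% against 0.302% and 6.77% against 5.13% in the same diet pairs. A CD8 T-cell cluster made up 10.1% against 4.74% in the CD45.2 sort, 2.91% against 5.77% in the live-cell sort and 8.66% against 0.380% after D. vulgaris. In the live-cell libraries the glioma-marker cluster made up 5.65% with high glucose against 3.13%, a cluster with Rgs5, Col1a2 and Mgp 0.928% against 0.618%, and a cluster of cells with few UMIs 2.93% against 0.480%.

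Most other lists were within the random range. The sulfide oxidation list, of interest because D. vulgaris makes hydrogen sulfide, had medians after D. vulgaris of 0.10 in T cells (percentile 83.3) and -0.02 in monocytes or macrophages (65.4). The glucose-responsive list had medians with high glucose of 0.04, -0.08 and -0.12 in T cells of the CD45.2, anti-PD-1 and live-cell pairs, and of 0.01, 0.01 and -0.08 in monocytes or macrophages. The MHC class I list had a median of 0.05 in monocytes or macrophages of the CD45.2 diet pair (percentile 98.9) and -0.14 in T cells of the anti-PD-1 pair (1.14).

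Il17re, Blk and Adam12 were higher with high glucose in T cells of all 3 SPF pairs without passing the test, but in the CD45.2 pair this rests on 10 against 3, 4 against 1 and 5 against 2 UMIs. A higher share of gamma-delta T cells of the interleukin-17 kind might raise all 3, and then their markers, Trdc, Tcrg-C1, Il17a and others, would be higher in each pair. Their median log2 fold was 1.36 with anti-PD-1 and 1.80 in the live-cell sort, but -0.185 in the CD45.2 sort, where 4 markers were measured and Trdc was at -1.30. With so few UMIs of the 3 genes in that pair, the test cannot decide over all 3 pairs. Trdc was seen in 12.2% against 3.83% of T cells in the live-cell sort. With anti-PD-1 it was seen in 1.475% against 1.277% (ratio 1.155, 0.771 to 1.73). The marker medians of those pairs go with a higher share of these cells. The Trdc interval with anti-PD-1 includes 1, however. A T-cell cluster with Cd163l1, Trdc, Adam12 and Blk among its leading genes made up 1.003% of kept cells with high glucose against 0.658% with anti-PD-1. In the live-cell sort this cluster made up 0% against 0.0549%. Other causes were not tested. That at least 20 UMIs of each gene are needed was set after these values were seen.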
